A study of Mus musculus with 9 samples.

How the data were processed

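The series holds 9 single-cell RNA-seq libraries of CD45+ cells, that is leukocytes, from the maxillary oral mucosa of C57BL/6 mice aged 16 weeks. By their titles, 3 libraries came from control mice, 3 from mice with periodontal disease and 3 from mice in recovery, and each library carries a replicate number. Per the labels' protocols, maxillary tissue was dissociated by hand and with collagenase, viable CD45+ cells were sorted, and each sample was loaded on its own lane with a 10x Chromium 3' kit. The labels do not say how many animals went into a library or that libraries came from separate animals. The p-values therefore measure only the spread between these libraries, which may be technical. The labels used here name no batch, run or sex.

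The deposited values are UMI counts, whole numbers per gene and barcode with no normalization, as the values themselves show. Per the submitters' processing notes, Cell Ranger 6.1 and the mouse genome build mm10 were used. How barcodes were chosen as cells is not given in the sources used here, and the smallest barcode held 500 UMIs. The 9 count tables list 32285 genes and 24425 barcodes with 300585565 UMIs. They carry no cell type annotation that was used here, so cell classes were rebuilt, and shares here rest on rebuilt names.

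Barcodes with fewer than 200 genes (139) or more than 10% mitochondrial UMIs (3608) were left out. Scrublet, run per library through scanpy 1.11.5, marked 19 of 24425 barcodes (0.078%) as doublets, too few for the caller to have worked. Those 19 were removed where they passed the other limits, and an alternative removed the 539 cells with the highest scores, at 0.8% of a library per 1000 barcodes. After all filters 20793 cells were kept. Counts were scaled to 10000 per cell and logged, and 2000 variable genes were reduced to 30 principal components. Cells were joined in a graph of 15 neighbours and clustered with Leiden at resolution 1.0 (igraph 0.11.9, seed 0), with no batch correction.

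The 27 clusters were named from 33 lists of markers fixed before the data were examined, as "X-like", from the highest mean score of at least 1.0 and at least 3 markers detected in 25% of cells. A cluster stayed unnamed when its median UMI count lay under a set fraction of its libraries' median with none of the name's markers among its 10 top genes, or when more of those genes marked another class. Folds for the top genes used a pseudocount of 10 CPM (scaled counts). Cluster 0 (4878 cells, median 569 UMIs), cluster 1 (513 cells, median 701 UMIs) and cluster 18 (95 cells, led by the B cell genes Ms4a1 and Cd79a with neutrophil markers detected) stayed unnamed. The other clusters gave 15 classes with 15307 cells.

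Leading genes by class were as follows. Neutrophil-like cells were clusters 4 (Mmp8, Retnlg, Fpr1), 6 (Mmp8, Mmp9, Cxcr2), 7 (Cstdc4, Nt5e, Retnlg) and 17 (Hcar2, Acod1, Ccrl2, Cxcl2, Nlrp3, Il1rn, genes of inflammatory activation). Neutrophil precursor-like cells were clusters 5 (Ltf, Ngp), 12 (Elane, Prtn3, Mpo) and 21 (Camp, Chil3, Fcnb). Monocyte-like cells were clusters 11 (Gria3, Lgals1, F13a1) and 14 (Vcan, Fn1, Clec4a3). B cell-like cells were clusters 8 (Ighd, Bank1) and 15 (Ms4a1, Cd79a), and B cell precursor-like cells were clusters 16 (Rag1), 23 (Vpreb1, Igll1, Lef1, Dntt) and 24 (Myl4, Igll1, Nrgn, Lef1). Single clusters made up the macrophage-like (20: Arg1, C1qa, Cxcl3, Cxcl1, Pdpn, Mmp14), conventional dendritic cell type 2-like (3: H2-Eb1, H2-Aa, Cd209a, Clec10a), plasmacytoid dendritic cell-like (2: Siglech, Ccr9), T cell-like (10: Cd3e, Trac), natural killer cell-like (22: Gzma, Il2rb, Klra8) and basophil-like (9: Prss34, Mcpt8) classes. The hematopoietic progenitor-like (13: Pf4, Ctla2a, Meis1), erythroid cell-like (19: Hbb-bs, Car1), osteoclast-like (25: Ctsk, Acp5) and plasma cell-like (26: Jchain, Ighg3) classes were also single clusters.

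Raw counts were summed per library over all kept cells, and per library and class where a class had at least 20 cells in a library and at least 2 such libraries per group. Sums were tested with edgeR 4.0.16 (R 4.3.3): TMM normalization, filterByExpr, glmQLFit with robust estimation and glmQLFTest, all 9 libraries in a single fit with the contrasts disease against control, recovery against disease and recovery against control. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within a class. Printed log2 fold changes carry the SE from the fit and edgeR's default prior count. The log2 CPM used for the gene lists had a prior count of 2. Levels are CPM as mean ± SD over libraries. A gene whose libraries in a group are at 0 or hold a few UMIs each is given as CPM with no fold. Class sizes were tested in edgeR with the number of kept cells as library size, and with a two-sided exact permutation test of the F statistic of logit shares over all 1680 assignments of the libraries to 3 groups. Between 2 groups of 3 libraries the exact test cannot go below p = 0.1.

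A set of 28 gene lists was fixed before the data were examined, together with the markers, the tests, the rule for named genes and the alternatives other than those named below as added. Lists with at least 5 tested genes were tested per class with limma 3.58.1 camera at a preset correlation of 0.01, adjusted over the 219 tests of a contrast. Camera with an estimated correlation and fry were alternatives. The lists are inflammatory cytokines and NF-kB targets, interferon-stimulated genes, interferon gamma response, MHC class II and class I presentation, type 17, type 1 and type 2 response, regulatory T cell genes, T cell activation and checkpoint, neutrophil granules, neutrophil activation and aging, osteoclast formation and function, and wound-healing and lipid-associated macrophage genes. The others are efferocytosis and resolution, complement, pattern recognition receptors, antimicrobial proteins, chemokine receptors and homing, B cell activation and antibody secretion, hypoxia and glycolysis, oxidative phosphorylation, ribosomal proteins, dissociation and immediate early genes, cell cycle, glucocorticoid-responsive genes, integrated and endoplasmic reticulum stress, and TGF-beta, matrix and tissue repair signals. The list genes Mx1 and Clec7a matched no symbol in the count tables and were not analysed here.

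Genes named in the text were chosen by a fixed rule. For each contrast it takes, over all cells, the 8 largest rises and 8 largest falls among called genes with at least 20 CPM in the higher group and no overlap between libraries. In each of the 3 classes with the most calls it takes 6 and 6 by the same conditions. For each list with a call it takes up to 4 members by smallest p, and where a part has no called gene the 4 genes of smallest p are given as values. Predicted gene models, immunoglobulin and T cell receptor segments, sex-linked, mitochondrial and haemoglobin genes were left out of the first parts, as were genes of a class under 10% of their highest class CPM, which free RNA could bring. Gene positions are on GRCm38 (mm10) from GENCODE mouse M21, joined by stable gene ID.

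The tests were first tested on simulated data: counts drawn from the real libraries' means with 200 genes changed by a fixed fold. For disease against control, edgeR recovered 56.5% of genes changed 2-fold over all cells (14180 genes), 62% in neutrophil-like (8935 genes), 74% in monocyte-like (11570 genes) and 12.5% in type 2 dendritic cells (6917 genes). At 4-fold these shares were 89.5% (14210 genes), 90.5% (8922 genes), 95% (11560 genes) and 74% (6918 genes). For recovery against disease they were 60%, 60%, 70% and 12.5% at 2-fold and 87%, 88%, 95.5% and 78% at 4-fold, over the same genes and classes. False calls made up, for disease against control, 8.13%, 5.34%, 5.13% and 19.4% of calls at 2-fold and 4.79%, 5.24%, 5.47% and 3.90% at 4-fold. For recovery against disease they made up 3.23%, 4.00%, 4.76% and 7.41% at 2-fold and 5.44%, 7.37%, 9.05% and 3.70% at 4-fold, in the order of classes above. Replicate libraries were compared over genes with at least 10 counts: their chi-square per degree of freedom lay between 22.8 and 125, so no pair agreed within sampling noise.

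Alternatives were at least 500 genes per cell, at most 5% mitochondrial UMIs, doublets kept, resolutions of 0.5 and 2.0, the replicate number as a block, each library left out in turn, only the 2 groups of a contrast in the fit, TMM factors for the shares, DESeq2 1.42.0 in place of edgeR, DESeq2 size factors in edgeR, no filter on low counts, at least 50 cells, adjustment over all classes together and free-RNA genes left out. Added after the data were seen were shares of named cells only, highest doublet scores removed, at least 10 cells per library and class, clusters by number, lists without free-RNA members, the macrophage-like class without each disease library, and clustering without its called genes. Recovery of disease genes was set against 20 simulations of unchanged groups that share the disease libraries. DESeq2 adjusted p-values given as NA stayed NA.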

Results

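Leukocytes of the maxillary oral mucosa, which surrounds the upper teeth, were profiled as single cells in control mice, in periodontal disease and in recovery. Each group had 3 libraries. The files held 5388, 3614 and 1324 barcodes in control libraries 1, 2 and 3, with 43456944, 36604846 and 21744385 UMIs. Disease libraries 1, 2 and 3 held 2812, 1396 and 2440 barcodes with 32737823, 21180199 and 32433865 UMIs. Recovery libraries 1, 2 and 3 held 3081, 2738 and 1632 barcodes with 38462162, 45754646 and 28210695 UMIs. After filtering, 4572, 3137 and 1121 control cells, 2244, 1223 and 2018 disease cells and 2673, 2291 and 1514 recovery cells were kept.

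The kept cells fell into 15 named classes led by neutrophils, monocytes, neutrophil precursors, B cell precursors and B cells. Hematopoietic progenitors, erythroid cells and neutrophil and B cell precursors, types known from bone marrow, were in every library. Marrow may have entered in amounts that differ, which was not tested. Clusters of low depth without a name held 44.9%, 42.2% and 5.35% of control libraries 1, 2 and 3. They held 22.6%, 21.1% and 17.1% of disease libraries and 23.8%, 8.99% and 6.47% of recovery libraries. Median UMIs per kept cell were 2151, 3961 and 11516 in controls, 7212.5, 8722 and 7585 in disease and 7309, 10739 and 12047.5 in recovery. This gap in depth and in unnamed cells stands beside every share below. Shares are of sorted CD45+ cells and say nothing about cells outside that gate.

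The first comparison asked how the leukocytes of diseased mucosa differed from those of control mucosa. Macrophage-like cells, the C1q-expressing phagocytes, made up 0.546% ± 0.105 of control cells and 4.25% ± 4.26 of disease cells (SD, n = 3). The log2 difference was 2.94 ± 0.72 (SE) with an edgeR adjusted p of 0.0324. The disease libraries held 0.980%, 2.70% and 9.07% of such cells, all above the highest control library. Macrophage markers summed over all cells stood at 412 ± 64.0 CPM in control and 592 ± 264 in disease, with 416 and 464 CPM in disease libraries 1 and 2, inside the control range. Neutrophil-like cells stood at 21.2% ± 7.10 in control and 32.0% ± 4.85 in disease, and monocyte-like cells at 9.57% ± 0.636 and 12.3% ± 0.859. Neither passed the edgeR test of the 16 class shares (adjusted p = 0.489 for both). T cell-like cells (1.90% ± 0.917 and 1.17% ± 0.111), natural killer cell-like cells (1.34% ± 0.465 and 0.884% ± 0.164), B cell-like cells (6.23% ± 0.954 and 4.20% ± 1.46) and B cell precursor-like cells (11.7% ± 6.18 and 7.81% ± 3.48) did not pass either, each with an adjusted p of 0.489. The macrophage call was lost without control library 1 (adjusted p = 0.168), 2 (0.208) or 3 (0.0891), disease library 3 (0.101) or recovery library 1 (0.0891) or 2 (0.0522). It was also lost with at least 500 genes per cell (0.0740), at resolution 0.5 (0.0531) and at resolution 2.0 (log2 1.00, adjusted p = 0.500). The same held with only the 2 groups in the fit (0.118), with TMM factors (0.0607), with named cells only (0.0798) and with the highest doublet scores removed (0.0522). The exact permutation p between the 2 groups was 0.1, the smallest possible. Genes that lead this cluster also differ between the groups. A clustering without the 636 genes called in it, added after the data were seen, gave 0.346% ± 0.118 in control and 3.73% ± 3.92 in disease, with a log2 difference of 3.40 ± 0.88 and an adjusted p of 0.0388.

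**Figure D1:**
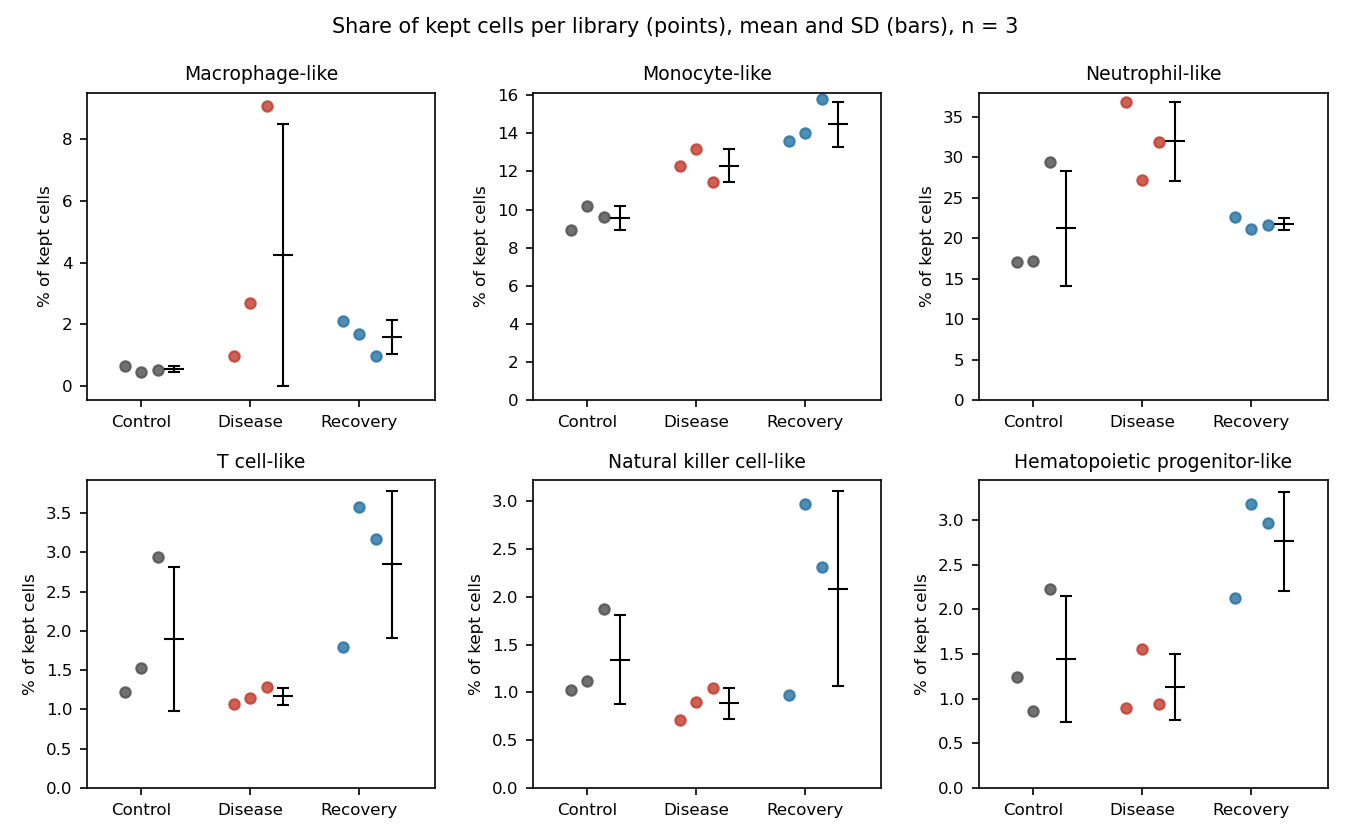
Share of kept CD45+ cells (percent, vertical axis) in 6 classes for control, disease and recovery, with points for the 3 libraries of each group and ticks with bars for mean ± SD. Macrophage-like cells reached 0.980%, 2.70% and 9.07% in the disease libraries against a mean of 0.546% in control and 1.60% in recovery.

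Over all cells together, the genes with the strongest statistical support for a difference were Nupr1, a stress-response regulator, at 13.8 ± 2.44 CPM in control and 32.5 ± 5.29 in disease (log2 1.23 ± 0.17), and Fabp5, a fatty acid carrier, at 47.6 ± 3.10 and 94.9 ± 16.6 CPM (log2 0.99 ± 0.15). Csf2rb2, a receptor chain of the interleukin-3 family, stood at 14.7 and 29.1 CPM and Prxl2b at 2.45 and 5.58 CPM. None of the 14404 genes passed edgeR, where the adjusted p of these 4 was 0.0779, with 1608 genes at an unadjusted p under 0.05 and 359 genes called by DESeq2, 282 of them higher in disease. The count rose to 278 without disease library 2 and to 1 without disease library 1 or 3. Summed eosinophil markers, measured beside these genes, stood at 163.5 ± 58.9 CPM in control, 48.2 ± 8.49 in disease and 79.9 ± 55.4 in recovery, and summed B cell markers at 639 ± 100.1, 342 ± 106 and 598 ± 98.3 CPM.

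Among classes with at least 20 cells per library, type 2 conventional dendritic cells (cluster 3, cells that present antigen to T cells) had the most calls. Of 7255 genes tested there, 55 rose and 9 fell in disease. The fixed rule names Fscn1, the actin-bundling fascin of mature dendritic cells, at 14.96 CPM in control library 2, 0 in the other 2 and 398 ± 180.0 CPM in disease (n = 2, adjusted p = 0.0495). Synpo2, an actin-binding protein, stood at 0.312 ± 0.540 and 39.5 ± 7.26 CPM (adjusted p = 0.00130), Adcy6, an adenylyl cyclase, at 0.312 and 32.4 CPM (adjusted p = 0.00751), and Adgb, the globin-like androglobin, at 0.731 and 28.95 CPM (adjusted p = 0.0142). Pfkfb3, which drives glycolysis, stood at 73.7 and 223 CPM (log2 1.55 ± 0.35, adjusted p = 0.0495). Htra1, a secreted protease, and Pakap had no UMI in any control library and stood at 37.9 ± 29.5 and 23.8 ± 11.4 CPM in disease (adjusted p = 0.00488 and 0.0315). Htra1 was not called by DESeq2 (adjusted p = 0.413).

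Genes that fell in these dendritic cells were Fkbp5, a glucocorticoid-induced chaperone of steroid receptors (108 ± 5.75 to 32.0 ± 14.9 CPM, log2 -1.81 ± 0.35, adjusted p = 0.0137), and P2ry14, a receptor for UDP-sugars (49.8 ± 9.68 to 5.71 ± 2.06 CPM, adjusted p = 0.0323). The tetraspanin Cd81 (64.0 to 14.3 CPM, log2 -2.06 ± 0.44, adjusted p = 0.0302) and the collagen-binding integrin chain Itga1 (63.2 to 16.7 CPM, adjusted p = 0.0403) fell. The sulfotransferase Sult1a1 (51.7 to 6.06 CPM, adjusted p = 0.0218) and Lsmem1 (44.1 to 3.91 CPM, adjusted p = 0.00520) fell as well. Outside the rule, chosen after their values were seen, 5 of the 9 markers on the fixed mature dendritic cell list were among the called genes and rose: Cd200 (3.88 to 117 CPM), Ccr7 (log2 3.52 ± 0.42), Il4i1 (log2 4.33 ± 0.55), Fscn1 and Cacnb3. Cacnb3, a calcium channel subunit, stood at 5.61 CPM in control library 2 and 0 in the others, against 48.9 and 64.5 CPM in disease (adjusted p = 0.00142). Over all cells those 9 markers summed to 65.5 ± 8.58 CPM in control, 79.5 ± 27.5 in disease and 72.6 ± 16.3 in recovery. Disease libraries 1, 2 and 3 held 100.4, 48.25 and 89.72 CPM, library 2 below every control. Il1rn, the interleukin-1 receptor antagonist, rose from 90.5 ± 26.9 to 420 ± 0.642 CPM (log2 2.19 ± 0.28, adjusted p = 0.000366).

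These dendritic calls rest on disease libraries 1 and 3 with 25 and 37 cells, since disease library 2 held 15 cells, and on 46, 62 and 27 control cells. Of the 64 genes 55 were called by DESeq2 and 3 remained when libraries with at least 10 cells brought disease library 2 in. Without control library 1, 2 or 3 there were 33, 37 and 34 calls, and without recovery library 3 there were 106. Without disease library 1 or 3 there were 40 and 26. Such fits hold a lone disease library, which is assumed to vary like the other groups.

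Single genes depended on single libraries in these dendritic cells. Synpo2 was called in each fit that left out a control or recovery library, and Htra1 in each of those that tested it. The fit without disease library 2 repeats the main fit, which never held it. Fits without disease library 1 or 3 hold a lone disease library, as above. Fkbp5 and Lsmem1 were lost only without disease library 3 (adjusted p = 0.332 and 0.181), Adgb without control library 2 (0.0603) and Adcy6 without disease library 1 or 3 (up to 0.194). Fscn1 was lost without control library 3, disease library 1 or 3 or recovery library 1 or 3 (adjusted p up to 0.165). P2ry14 was lost without control library 1, 2 or 3, disease library 1 or 3 or recovery library 1 (up to 0.278). Pfkfb3 was lost without control library 1 or 3, disease library 1 or recovery library 1 (up to 0.568). Without control library 1 or 3 or disease library 1 or 3, Sult1a1 and Cd81 were lost (up to 0.308 and 0.273). Pakap and Itga1 were lost without those and without control library 2 (up to 0.263 and 0.513).

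**Figure D2:**
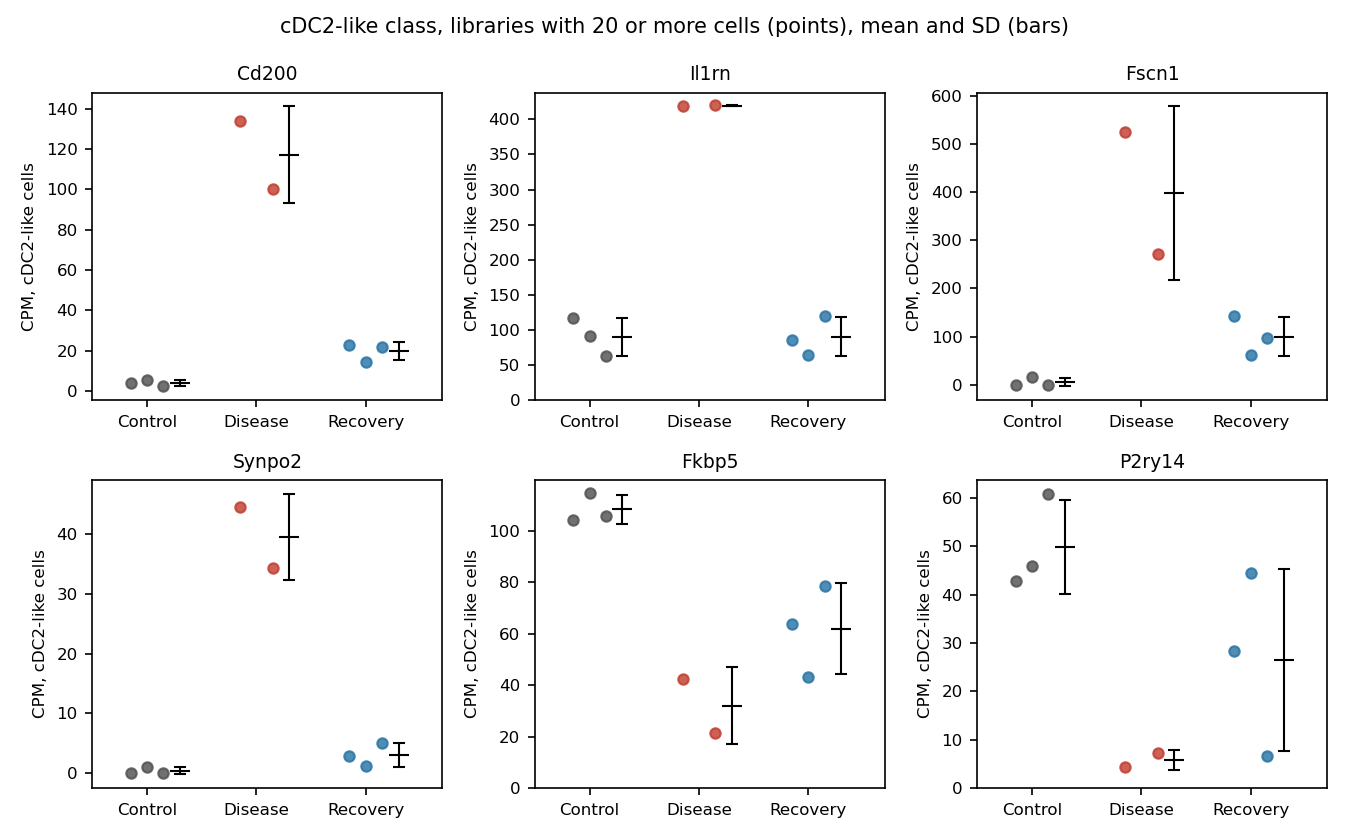
Expression (CPM, vertical axis) of Cd200, Il1rn, Fscn1, Synpo2, Fkbp5 and P2ry14 in type 2 dendritic cell-like cells, with points for libraries (3 control, 2 disease, 3 recovery) and ticks with bars for mean ± SD. Il1rn stood at a mean of 90.5 CPM in control, 420 in disease and 90.6 in recovery.

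In monocyte-like cells (clusters 11 and 14), 4 of 11669 genes rose and 1 fell. Fpr1, the receptor for bacterial formyl peptides, rose from 11.9 ± 3.41 to 35.8 ± 8.89 CPM (log2 1.62 ± 0.23, adjusted p = 0.0285, n = 3), and the chemokine Ccl4 from 96.6 ± 18.8 to 189.5 ± 21.2 CPM (log2 0.98 ± 0.16, adjusted p = 0.0464). The other 3 called genes fall outside the rule and were chosen after their values were seen: Il1f9, an interleukin-1 family cytokine (20.6 to 69.1 CPM, log2 1.80 ± 0.26), Trim30b (12.7 to 26.9 CPM, log2 1.08 ± 0.18) and the B cell gene Ms4a1 (5.65 to 1.06 CPM, log2 -2.47 ± 0.38). Values that did not pass include Gadd45b at 121 and 282 CPM (adjusted p = 0.0782) and Cd274, the ligand of PD-1, at 12.6 and 32.1 CPM (adjusted p = 0.152). All 5 called genes were also called by DESeq2, and all 5 lay under 10% of their highest class CPM, the limit set for free RNA. Without disease library 2 the count was 101 and without control library 3 it was 9, while it fell to 0 without control library 1 or recovery library 2, to 1 without control library 2 or recovery library 3 and to 2 without disease library 1. Fpr1 was lost without control library 1 or 2 or recovery library 2 or 3 (adjusted p up to 0.105), and Ccl4 without those and without disease library 1 or 3 (up to 0.236).

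Neutrophil-like cells (clusters 4, 6, 7 and 17) had no called gene among 9049 in edgeR, with 805 at an unadjusted p under 0.05 and 91 called by DESeq2. Cluster 17, led by Acod1, Cxcl2, Nlrp3 and Il1rn, held 27.2% ± 7.13 of them in control, 44.0% ± 7.43 in disease and 28.8% ± 6.28 in recovery. Cluster 4, led by Mmp8 and Retnlg, held 35.7% ± 7.22, 24.7% ± 3.51 and 33.0% ± 3.06. Neutrophil precursor-like cells had 0 calls in edgeR (450 genes at an unadjusted p under 0.05, 20 by DESeq2), with Csf1r, the receptor of macrophage colony-stimulating factor, at log2 0.90 ± 0.15 (adjusted p = 0.119). B cell-like (310 unadjusted, 0 by DESeq2), B cell precursor-like (197 and 0), basophil-like (218 and 1) and T cell-like cells (370 and 4) also had 0 edgeR calls. Without disease library 2 the count was 29 in neutrophil-like and 21 in precursor-like cells, and without disease library 1 it was 3, 2 and, in T cell-like cells, 4. It was 5 in T cell-like cells without control library 1, 2 in basophil-like cells without control library 2, 2 in neutrophil-like cells without control library 3, and 0 or 1 in the other fits. T cell-like cells had 2 disease libraries (1 and 3) and basophil-like cells 2 control libraries (1 and 2), so fits without 1 of these hold a lone library, assumed to vary like the other groups.

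Among the fixed gene lists, the inflammatory cytokines and NF-kB targets, early response genes of innate cells, rose in 6 of 8 classes in disease. In monocyte-like cells 26 of 27 members had a positive log2 fold change with a median of 0.95, 1 was called over all genes and 18 adjusted over the list alone (camera adjusted p = 7.77e-18, but adjusted p = 0.492 with an estimated correlation). Il1a, the cytokine interleukin-1 alpha, stood there at 4.57 and 19.0 CPM (log2 2.19 ± 0.44, adjusted p = 0.136) and Nlrp3, a sensor of the inflammasome, at 139.6 and 269 CPM (log2 0.95 ± 0.21, adjusted p = 0.152). The median was 0.83 in neutrophil-like cells with 25 of 27 positive, 0 called over all genes and 12 adjusted over the list alone (adjusted p = 0.561 with an estimated correlation). Over clusters tested apart its mean was 0.289, with -0.169 in cluster 6 and -0.143 in cluster 7. It was 0.75 in neutrophil precursor-like cells with 26 of 27 positive, 0 called and 8 adjusted over the list alone, and 0.82 in T cell-like cells with 18 of 22 positive, 0 called and 5 adjusted over the list alone. It was 0.57 in type 2 dendritic cells with 20 of 26 positive, 3 called and 4 adjusted over the list alone, and 0.27 in B cell-like cells with 17 of 19 positive, 0 called and 1 adjusted over the list alone. With an estimated correlation the adjusted p lay between 0.492 and 0.561 in these classes. In T cell-like cells Il1b and Cxcl2, genes that neutrophils express strongly, stood at 156 and 533 CPM in control and 1035 and 1986 in disease, so free RNA or doublets stand beside that class's values.

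Neutrophil activation and aging genes rose in 6 classes, and free RNA of neutrophils could bring them to other cells. The median was 0.80 in monocyte-like cells (23 of 24 positive, 1 called, 17 adjusted over the list alone). It was 0.67 in neutrophil-like cells (20 of 24, 0 and 10), both with an adjusted p of 0.492 with an estimated correlation. In monocyte-like cells the receptor genes Cxcr2 (log2 0.85, adjusted p = 0.0895), Fpr2 (log2 0.76, adjusted p = 0.189) and C5ar1 (log2 0.79, adjusted p = 0.165) did not pass singly. Interferon gamma response genes rose in 5 classes, in neutrophil-like cells with all 15 members positive at a median of 0.66, 0 called and 4 adjusted over the list alone (adjusted p = 0.522 with an estimated correlation). Cd274 stood there at 58.3 ± 4.87 and 132 ± 67.3 CPM (adjusted p = 0.222) and the guanylate-binding protein Gbp2 at 7.47 and 18.6 CPM (adjusted p = 0.261). Interferon-stimulated genes rose in 4 classes (median 0.69 in neutrophil-like cells, 25 of 27 positive, 0 called, 6 adjusted over the list alone, adjusted p = 0.747 with an estimated correlation). Pattern recognition receptors rose in 4 (median 0.33 in monocyte-like cells, 24 of 28 positive, 1 called, 6 adjusted over the list alone, adjusted p = 0.561 with an estimated correlation). The complement list passed in monocyte-like cells, 1 of 8 classes, with 11 of 12 members positive, a median of 0.73, 0 called and 6 adjusted over the list alone (adjusted p = 0.492 with an estimated correlation). Its median was positive in 6 of the 8 classes, and the difference between classes was not tested.

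The remaining lists moved in fewer classes. MHC class I presentation rose in 3 (in neutrophil-like cells H2-Q4 stood at 13.4 and 24.5 CPM, adjusted p = 0.218), oxidative phosphorylation in 3, osteoclast formation and function in 3, dissociation and immediate early genes in 3, antimicrobial proteins in 2 and chemokine receptors in 1. Hypoxia and glycolysis rose in 2, in dendritic cells with 18 of 23 positive, 1 called and 4 adjusted over the list alone. MHC class II presentation rose in 2, among them T cell-like cells, whose Cd74 (162 ± 112 and 932 ± 786 CPM) and H2-Eb1 (30.2 and 282 CPM) are genes of antigen-presenting cells that stayed under 10% of their highest class level. Wound-healing and lipid-associated macrophage genes rose in 2. Ribosomal proteins rose in 1 class and fell in 2, cell cycle genes rose in 1 and fell in 2, efferocytosis and resolution genes rose in 2 and fell in 1, and neutrophil granules fell in 1. These calls had adjusted p-values from 0.492 to 0.902 with an estimated correlation. Of 219 list tests 51 rose and 6 fell, and none passed with an estimated correlation (lowest adjusted p = 0.492, 19 at an unadjusted p under 0.05) or with fry (lowest adjusted p = 0.306). Lists with no call were type 17, type 1 and type 2 response, regulatory T cell genes, T cell activation, B cell activation, glucocorticoid-responsive genes, endoplasmic reticulum stress and TGF-beta and matrix signals, whose class medians ran from -1.29 for type 2 response to 0.75 for regulatory T cell genes.

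The second comparison asked what differed between recovery and disease. Over all cells, 40 genes rose and 114 fell in recovery. Among those that fell was Nlrp3, from 342 ± 95.3 to 111 ± 14.6 CPM (log2 -1.63 ± 0.22, adjusted p = 0.0178, n = 3). Acod1, which makes itaconate in activated myeloid cells, fell from 832 ± 259 to 257 ± 53.3 CPM (log2 -1.69 ± 0.24, adjusted p = 0.0186). Il1b, the cytokine interleukin-1 beta, fell from 1661 ± 585 to 617 ± 106 CPM (log2 -1.43 ± 0.24, adjusted p = 0.0283), and Ptgs2, the inducible prostaglandin synthase, from 373 ± 163 to 99.3 ± 26.2 CPM (log2 -1.91 ± 0.32, adjusted p = 0.0303). Control levels were 149, 352, 731 and 146 CPM in the same order. Pla2g7, a lipase that inactivates platelet-activating factor (log2 -1.62 ± 0.24, adjusted p = 0.0230), Ifitm1, an interferon-induced membrane protein (log2 -1.32 ± 0.24, adjusted p = 0.0324), Il13ra1, a receptor chain for interleukin-13 (log2 -1.39 ± 0.22, adjusted p = 0.0283), and Ms4a6d (log2 -1.71 ± 0.33, adjusted p = 0.0462) fell too. Acod1 and Nlrp3 are among the genes that lead neutrophil cluster 17, whose share of neutrophil-like cells is given above.

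Among the genes that rose were Igll1 and Vpreb1, the surrogate light chain of the pre-B cell receptor. They went from 16.6 ± 3.25 to 64.0 ± 5.32 CPM (log2 1.95 ± 0.24, adjusted p = 0.0178) and from 21.6 ± 4.49 to 76.7 ± 15.1 CPM (log2 1.82 ± 0.25, adjusted p = 0.0186), with control levels of 29.8 ± 10.9 and 33.0 ± 11.3 CPM. The transcription factor Lef1 (log2 1.38 ± 0.26, adjusted p = 0.0396), Nrgn (log2 1.44 ± 0.21, adjusted p = 0.0213), Ctla2a (log2 1.85 ± 0.30, adjusted p = 0.0283), the interleukin-2 receptor chain Il2rb (log2 1.43 ± 0.27, adjusted p = 0.0391), Gramd3 (log2 0.87 ± 0.15, adjusted p = 0.0283) and the histone gene Hist1h2ap (206 ± 30.1 to 677 ± 267 CPM, log2 1.71 ± 0.30, adjusted p = 0.0321) also rose. Igll1, Vpreb1, Lef1 and Nrgn lead B cell precursor clusters, Ctla2a the hematopoietic progenitor cluster and Il2rb the natural killer cell cluster. These sums mix the shares of those classes, which marrow could change, with levels within cells, and the 2 were not separated. B cell precursor-like cells were 7.81% ± 3.48 of disease and 13.8% ± 0.725 of recovery cells (edgeR adjusted p = 0.193). Histone genes such as Hist1h2ap belong to a family of near-identical copies, so their counts are uncertain.

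All 154 genes were called by DESeq2, which called 983. With edgeR 16 were called with only the 2 groups in the fit. The count depends on single libraries: it was 83 without control library 1, 19 without control library 2, 1 without disease library 1, 666 without disease library 2, 22 without disease library 3, 416 without recovery library 1, 0 without recovery library 2 and 5 without recovery library 3. Igll1, Vpreb1, Nrgn, Nlrp3, Acod1 and Ctla2a were lost without disease library 1 or recovery library 2 or 3, with adjusted p-values up to 0.120, 0.131, 0.147, 0.147, 0.148 and 0.173. Pla2g7 was lost there and without disease library 3 (up to 0.148). Il1b, Ptgs2, Il13ra1, Gramd3 and Hist1h2ap were lost there and without control library 2 or disease library 3 (up to 0.173 each), and Lef1 also without recovery library 1 (up to 0.173). Il2rb was lost without control library 1, 2 or 3, disease library 1 or recovery library 2 or 3 (up to 0.173). Ms4a6d and Ifitm1 were kept only without control library 3 or disease library 2 (up to 0.208 and 0.180 without control library 1 or 2, disease library 1 or 3 or recovery library 1, 2 or 3).

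**Figure D3:**
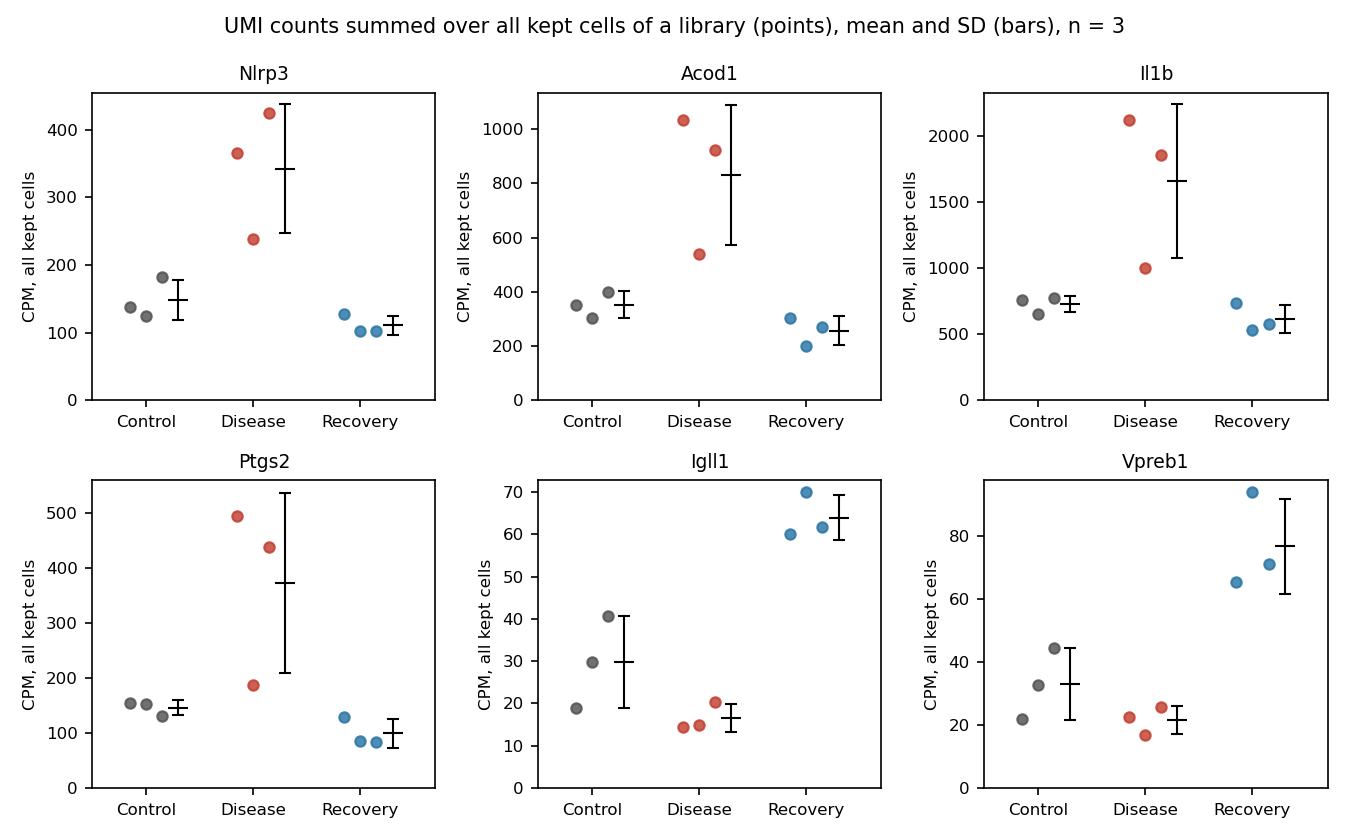
Expression summed over all kept cells (CPM, vertical axis) of Nlrp3, Acod1, Il1b, Ptgs2, Igll1 and Vpreb1, with points for the 3 libraries of each group and ticks with bars for mean ± SD. Nlrp3 stood at a mean of 149 CPM in control, 342 in disease and 111 in recovery, and Igll1 at 29.8, 16.6 and 64.0.

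Positions on GRCm38 of the main genes are as follows. Nlrp3 (ENSMUSG00000032691) lies on chromosome 11 from 59541568 to 59566956, Acod1 (ENSMUSG00000022126) on chromosome 14 from 103046977 to 103056573, Il1b (ENSMUSG00000027398) on chromosome 2 from 129364570 to 129371139 and Ptgs2 (ENSMUSG00000032487) on chromosome 1 from 150100031 to 150108227. Igll1 (ENSMUSG00000075370) and Vpreb1 (ENSMUSG00000059305) are neighbours on chromosome 16, from 16860671 to 16863985 and from 16868403 to 16870843. Cd200 (ENSMUSG00000022661) lies on chromosome 16 from 45382135 to 45409053 and Il1rn (ENSMUSG00000026981) on chromosome 2 from 24336853 to 24351494. All are annotated as protein-coding genes, and 3' tag counts do not say which exons were read.

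Among class shares, none passed edgeR between recovery and disease. Macrophage-like cells stood at 4.25% ± 4.26 in disease and 1.60% ± 0.560 in recovery (log2 -1.40 ± 0.67, adjusted p = 0.162) and neutrophil-like cells at 32.0% ± 4.85 and 21.8% ± 0.751 (log2 -0.55 ± 0.33, adjusted p = 0.241). T cell-like cells stood at 1.17% ± 0.111 and 2.85% ± 0.934 (log2 1.28 ± 0.43), natural killer cell-like cells at 0.884% ± 0.164 and 2.08% ± 1.02 (log2 1.23 ± 0.47), hematopoietic progenitor-like cells at 1.13% ± 0.369 and 2.76% ± 0.557 (log2 1.31 ± 0.43) and erythroid cell-like cells at 0.255% ± 0.0382 and 0.620% ± 0.193 (log2 1.23 ± 0.45), each with an adjusted p of 0.0963. B cell-like cells stood at 4.20% ± 1.46 and 7.97% ± 3.33 (adjusted p = 0.147). With unnamed cells left out of the denominator, an alternative added after the data were seen, 5 shares passed: progenitors (log2 1.19), T cells (1.14), natural killer cells (1.08) and erythroid cells (1.10) rose and neutrophils fell (log2 -0.67). Without recovery library 1, control library 3 or disease library 1, 4, 2 and 1 shares passed.

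In neutrophil-like cells (clusters 4, 6, 7 and 17) 2 genes rose and 9 fell in recovery, of 9049. Olr1, a receptor for oxidised lipoprotein, fell from 128 ± 13.8 to 52.6 ± 9.60 CPM (log2 -1.28 ± 0.17, adjusted p = 0.00771) and Nlrp3 from 887 ± 222 to 359 ± 23.5 CPM (log2 -1.30 ± 0.21, adjusted p = 0.0250). The signalling adaptor Cass4 fell from 28.2 to 10.3 CPM (log2 -1.43 ± 0.23, adjusted p = 0.0250) and the histone methyltransferase Dot1l from 98.6 to 43.5 CPM (log2 -1.18 ± 0.19, adjusted p = 0.0250). Il13ra1 (log2 -1.22 ± 0.18, adjusted p = 0.0169) and Clec2d, a C-type lectin (log2 -1.17 ± 0.21, adjusted p = 0.0371), fell as well. Nlrp3 leads cluster 17, whose shares are given above. All 11 genes were called by DESeq2, which called 113, and 3 of them, with both that rose, lay under the free-RNA limit of 10%. Without control library 1, 2 or 3 the count was 32, 20 and 21, without disease library 1, 2 or 3 it was 2, 73 and 1, and without recovery library 2 or 3 it was 0 and 3. Olr1 was lost only without recovery library 2 (adjusted p = 0.0916), and Nlrp3 and Clec2d without disease library 1 or 3 or recovery library 1, 2 or 3 (up to 0.197 for both). Il13ra1 was lost without disease library 1 or 3 or recovery library 2 (up to 0.130), Dot1l there and without recovery library 3 (up to 0.197), and Cass4 without disease library 3 or recovery library 2 or 3 (up to 0.197).

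**Figure D4:**
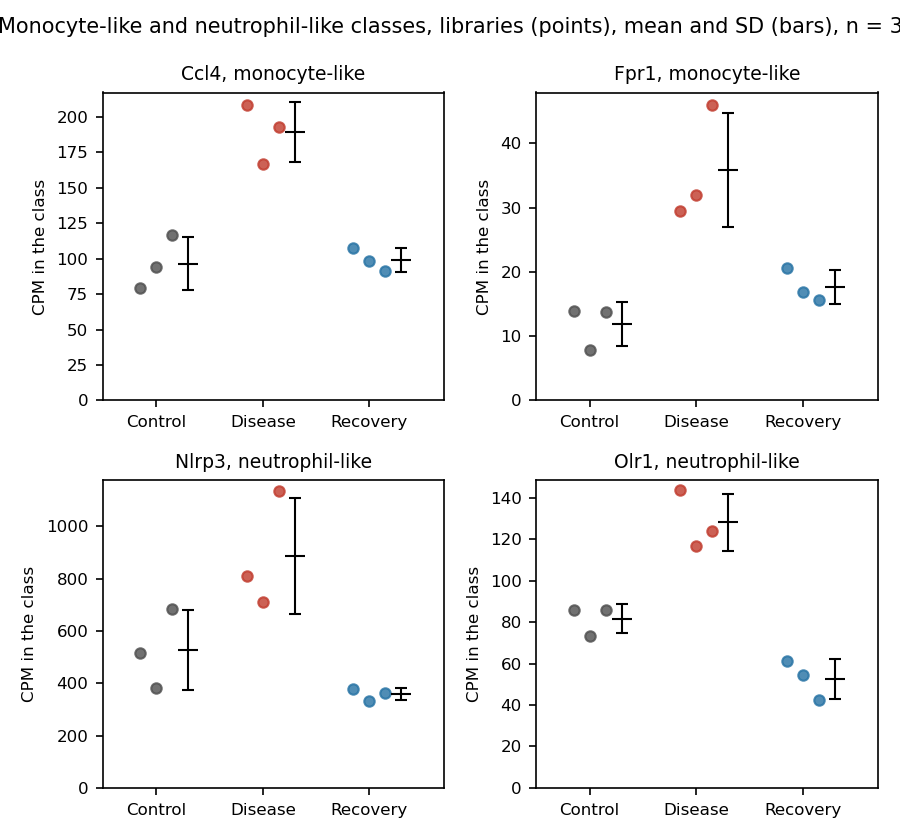
Expression (CPM, vertical axis) of Ccl4 and Fpr1 in monocyte-like cells and of Nlrp3 and Olr1 in neutrophil-like cells, with points for the 3 libraries of each group and ticks with bars for mean ± SD. Olr1 stood at a mean of 81.7 CPM in control, 128 in disease and 52.6 in recovery.

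In type 2 dendritic cells 12 of 7255 genes fell in recovery and none rose. Cd200, a ligand that restrains myeloid cells, fell from 117 ± 23.8 CPM (n = 2) to 19.6 ± 4.51 (n = 3), with 3.88 ± 1.68 in control (log2 -2.59 ± 0.34, adjusted p = 0.000704). Il1rn fell from 420 ± 0.642 to 90.6 ± 28.0 CPM (log2 -2.23 ± 0.28, adjusted p = 0.000667) and Synpo2 from 39.5 to 2.96 CPM (adjusted p = 0.0248). Chst11, a chondroitin sulfotransferase, fell from 59.6 to 9.23 CPM (log2 -2.67 ± 0.47, adjusted p = 0.0157), as did the lysosomal phosphatase Acp2 (log2 -2.26 ± 0.44, adjusted p = 0.0359). Htra1 fell from 37.9 to 0.945 CPM (adjusted p = 0.0333). DESeq2 called 10 of the 12 (29 in all), and 1 remained when libraries with at least 10 cells were used. The count was 23 without control library 2, 5 without disease library 3, 34 without recovery library 1, 3 without recovery library 2 and 23 without recovery library 3, and Cd200 and Il1rn were called in all 9 such fits. Those without disease library 1 or 3 hold a lone disease library, as above. Chst11 was lost without disease library 3 or recovery library 2 (adjusted p up to 0.367), Synpo2 there and without disease library 1 (up to 0.367), Htra1 without recovery library 2 or 3 (up to 0.130) and Acp2 without disease library 3 or recovery library 1, 2 or 3 (up to 0.670).

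Elsewhere, basophil-like cells had 1 call, Hist1h2ap, chosen after its values were seen (log2 2.71 ± 0.33, adjusted p = 0.00365), which was lost without disease library 3 or recovery library 3 (count 0), while the count was 2 without control library 1 or 2, disease library 2 or recovery library 2. Neutrophil precursor-like cells had 2 calls, chosen here after their values were seen: Il1a fell (log2 -3.38 ± 0.49, adjusted p = 0.0330) and the light chain gene Iglc1, an antibody gene of plasma cells, rose (adjusted p = 0.00246). Iglc1 stood at 0.238, 0.615 and 0.576 CPM in the disease libraries and 11.6, 11.9 and 6.46 CPM in recovery. Both genes lay under the free-RNA limit. That count was 12 without disease library 2, 0 without disease library 1 and 1 without control library 1, 2 or 3 or recovery library 1, 2 or 3. By rule, values there that did not pass were Hist1h2ap at 383 and 1135 CPM (adjusted p = 0.260) and Klra2 at 13.6 and 7.41 CPM (adjusted p = 0.470). Monocyte-like cells had 0 edgeR calls (1498 genes at an unadjusted p under 0.05, 91 by DESeq2), with Ccl4 at log2 -0.93 ± 0.16 and Nlrp3 at log2 -1.19 ± 0.21 (adjusted p = 0.0824 for both). B cell precursor-like (1629 unadjusted, 10 by DESeq2), B cell-like (809 and 0) and T cell-like cells (314 and 1) had 0 edgeR calls. Left-out libraries raised these counts to 181 in monocyte-like cells without disease library 2, 29 without recovery library 1, 4 without control library 2, 3 without disease library 3 and 2 in B cell precursor-like cells without recovery library 1, and to 0 or 1 in the other fits.

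The inflammatory cytokines and NF-kB targets fell in recovery in 5 of 8 classes. In neutrophil-like cells 26 of 27 members were negative at a median of -1.06, 1 was called (Nlrp3) and 13 adjusted over the list alone. Genes short of the threshold singly were Ptgs2 (808 ± 254 to 367 ± 76.6 CPM, adjusted p = 0.0567), Nfkbiz, an atypical inhibitor of NF-kB (1064 ± 335 to 512 ± 69.8 CPM, adjusted p = 0.0617), and Tnfaip3, a brake on NF-kB signalling (602 ± 161 to 289 ± 49.2 CPM, adjusted p = 0.0716). In monocyte-like cells 25 of 27 were negative at a median of -0.93, with 0 called and 17 adjusted over the list alone. Medians were -0.75 in neutrophil precursor-like cells (23 of 27 negative, 1 called, 4 adjusted over the list alone), -0.73 in T cell-like cells (20 of 22 negative, 0 called) and -0.36 in B cell precursor-like cells (15 of 20 negative, 0 called), the last 2 with 0 adjusted over the list alone. With an estimated correlation the adjusted p was 0.865 to 0.936. Neutrophil activation and aging genes fell in 4 classes, with all 24 members negative in neutrophil-like (median -0.86, 1 called, 14 adjusted over the list alone) and in monocyte-like cells (median -0.59, 0 called, 16 adjusted over the list alone). Pattern recognition receptors fell in 4 (median -0.38 in monocyte-like cells, 27 of 28 negative, 0 called, 10 adjusted over the list alone), interferon-stimulated genes in 3 (median -0.85 in neutrophil-like cells, 25 of 27 negative, 0 called, 15 adjusted over the list alone), interferon gamma response genes in 2 and complement in 1, all with an adjusted p of 0.865 with an estimated correlation in the classes where they fell. In neutrophil-like cells Oasl2, an interferon-induced gene, stood at 69.4 ± 28.1 and 31.6 ± 6.36 CPM (adjusted p = 0.0716).

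Ribosomal protein genes rose in recovery over disease in all 8 classes, each with all 32 members positive and class medians from 0.32 to 0.69. Median mitochondrial UMIs were 2.31%, 2.27% and 2.32% in disease libraries, 2.69%, 2.68% and 2.53% in recovery and 2.04%, 2.00% and 2.58% in control. None was called over all genes, while 29 in B cell precursor-like, 24 in dendritic, 23 in basophil-like and 23 in monocyte-like cells passed adjusted over the list alone (adjusted p from 0.865 to 0.936 with an estimated correlation). Oxidative phosphorylation genes, which code for the respiratory chain, rose in 6 classes (median 0.54 in B cell precursor-like cells, all 28 positive, 0 called, 14 adjusted over the list alone, and adjusted p = 0.865 with an estimated correlation). MHC class II presentation rose in monocyte-like cells (median 0.63, 10 of 12 positive, 0 called, 5 adjusted over the list alone, adjusted p = 0.865 with an estimated correlation), with Cd74, the invariant chain, at 466 CPM in disease and 867 in recovery (adjusted p = 0.139). Single classes gave a rise in type 17 response, neutrophil granules, antimicrobial proteins, glucocorticoid-responsive and dissociation genes, and a fall in osteoclast genes and T cell activation genes, while hypoxia and cell cycle genes rose in 1 class and fell in another (adjusted p from 0.865 to 0.904 with an estimated correlation). In neutrophil-like cells Csf1r, of the osteoclast list, stood at 53.0 ± 3.45 and 29.3 ± 4.86 CPM (adjusted p = 0.0617), and Nr4a1, of the T cell activation list, an immediate early gene of many cells, at 455 and 299 CPM (adjusted p = 0.0953). Of 219 tests 22 rose and 23 fell, with none past the threshold with an estimated correlation (lowest adjusted p = 0.865, 10 at an unadjusted p under 0.05) or with fry (lowest adjusted p = 0.343). MHC class I, type 1, type 2, regulatory T cell, B cell activation, efferocytosis, wound-healing, chemokine receptor, endoplasmic reticulum stress and TGF-beta lists had no call, with class medians from -0.66 for chemokine receptors to 1.05 for type 2 response.

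The third comparison asked where recovery still differed from control. No class share passed edgeR. Monocyte-like cells stood at 9.57% ± 0.636 in control and 14.5% ± 1.17 in recovery (log2 0.60 ± 0.28, adjusted p = 0.243), hematopoietic progenitor-like cells at 1.45% ± 0.706 and 2.76% ± 0.557 (log2 0.98 ± 0.42, adjusted p = 0.243) and macrophage-like cells at 0.546% ± 0.105 and 1.60% ± 0.560 (log2 1.54 ± 0.72, adjusted p = 0.243). In the exact permutation test of all 3 groups, monocyte shares gave p = 0.00357, the smallest possible, with an adjusted p of 0.0571 over the 16 classes. With unnamed cells left out they were 14.6%, 15.5% and 16.7% in control, disease and recovery (exact p = 0.714), and monocyte markers over all cells stood at 2866, 3463 and 2754 CPM. T cell shares gave an exact p of 0.0429 and an adjusted p of 0.229 there. Neutrophil precursor-like cells (10.8% ± 4.19, 11.4% ± 2.14 and 12.98% ± 3.02 in control, disease and recovery), basophil-like cells (1.03% ± 0.351, 1.65% ± 0.628 and 1.66% ± 0.658), plasmacytoid dendritic cell-like cells (1.04% ± 0.756, 0.903% ± 0.522 and 1.57% ± 0.436) and type 2 dendritic cells (1.80% ± 0.718, 1.39% ± 0.387 and 2.19% ± 0.497) passed no test in any comparison. Osteoclast-like cells (0.121%, 0.208% and 0.286%) and plasma cell-like cells (0.0947%, 0.222% and 0.292%) were rare throughout.

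Over all cells, edgeR called none of 14404 genes between recovery and control, with 1622 at an unadjusted p under 0.05 and 23 called by DESeq2. The smallest p-values belonged to Vpreb2, a gene of the surrogate light chain (3.67 and 10.8 CPM, log2 1.58 ± 0.26), Fabp5 (47.6 and 89.1 CPM, log2 0.90 ± 0.15), the natural killer receptor Klra5 (0.0168 and 0.526 CPM) and the peroxidase Prdx4 (24.1 and 39.6 CPM, log2 0.72 ± 0.12), all with an adjusted p of 0.284. Leaving out any 1 library left this count at 0.

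Within classes 5 genes were higher and 2 lower in recovery than in control. In type 2 dendritic cells Ly75, the endocytic receptor DEC-205, stood at 11.5 CPM in control, 89.6 in disease and 49.7 in recovery (log2 2.16 ± 0.35, adjusted p = 0.0469) and Basp1 at 150.1, 426 and 378 CPM (log2 1.33 ± 0.23, adjusted p = 0.0473). That count was 0 without control library 1 or 3, 4 without control library 2, 1 without recovery library 1 or 3 and 5 without recovery library 2, with Ly75 lost without control library 1, 2 or 3 or recovery library 1 or 2 (adjusted p up to 0.173). Basp1 was lost without control library 1, 2 or 3, disease library 1 or 3 or recovery library 1 or 3 (up to 0.364). Hist1h2ap, chosen after its values were seen, rose in B cell-like cells (log2 2.44 ± 0.33, adjusted p = 0.00138) and in neutrophil-like cells (log2 2.07 ± 0.24, adjusted p = 0.00181). Both calls and that of Iglc1 below lay under the free-RNA limit, against 1135 CPM of Hist1h2ap in neutrophil precursor-like cells, and 2 of the 5 rises were left without such genes. By rule, Tuba1c, an alpha tubulin, is given as a value in B cell-like cells (22.8 and 50.7 CPM, adjusted p = 0.579). In basophil-like cells (2 control libraries) the non-coding transcripts AY036118 (551 to 148 CPM, log2 -1.87 ± 0.29, adjusted p = 0.0198) and Gm42418 (log2 -1.64 ± 0.21, adjusted p = 0.00250, chosen after its values were seen) fell. Both are known to carry reads of ribosomal RNA, and AY036118 was lost without control library 2 (adjusted p = 0.0764) or recovery library 1 (0.0951). Iglc1 rose in neutrophil precursor-like cells (log2 2.82 ± 0.38, adjusted p = 0.0331, chosen after its values were seen), and this call was lost in every fit that left out a library except those without control library 2 or recovery library 3. The basophil count was 4 without control library 1, 6 without control library 2 (both with a lone control library, assumed to vary like the other groups) and 1 without recovery library 1, the B cell count 2 without control library 3 or recovery library 1, and the neutrophil count 2 without recovery library 3.

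B cell precursor-like cells had 0 edgeR calls between recovery and control, with 2199 of 10404 genes at an unadjusted p under 0.05, 468 called by DESeq2 and 1017 called by edgeR without recovery library 1. On the hypoxia and glycolysis list the smallest p there belonged to Ldha (151 and 329.7 CPM, log2 1.13 ± 0.28), Gapdh (log2 1.03 ± 0.27), Tpi1 (log2 0.93) and the cytokine gene Mif (log2 1.21), each with an adjusted p of 0.111. Monocyte-like (1506 unadjusted, 11 by DESeq2) and T cell-like cells (332 and 2) also had 0 edgeR calls, and at most 2 without any 1 library. In B cell precursor-like cells without disease library 3 the count was 1.

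Among the gene lists, ribosomal protein and oxidative phosphorylation genes were higher in recovery than in control in all 8 classes, with class medians from 0.39 to 0.77 and from 0.25 to 0.73 and adjusted p-values from 0.926 to 0.946 with an estimated correlation. None of their members was called over all genes. In B cell precursor-like cells all 32 ribosomal and all 28 respiratory genes passed adjusted over the list alone, as did 21 ribosomal genes in basophil-like and 10 in neutrophil-like cells. MHC class II presentation was higher in T cell-like cells (9 of 9 members positive, median 3.07, 0 called, 5 adjusted over the list alone), and in monocyte-like cells (median 0.36, 11 of 12 positive, 0 called), each with an adjusted p of 0.926 with an estimated correlation. In T cell-like cells H2-DMa stood at 10.1 ± 1.20 and 59.3 ± 28.7 CPM (adjusted p = 0.611) and Cd74 at 162 ± 112 and 1386 ± 915. Both are genes of antigen-presenting cells, and Cd74 stayed under 10% of its highest class level. MHC class I presentation was higher in 4 classes, antimicrobial proteins in 3, neutrophil granules, hypoxia and endoplasmic reticulum stress in 2 each, and type 17, wound-healing, cell cycle, inflammatory, interferon-stimulated and interferon gamma lists in 1 each (adjusted p from 0.926 to 0.940 with an estimated correlation). All 37 calls among 219 tests were rises. None passed with an estimated correlation (lowest adjusted p = 0.926, 3 at an unadjusted p under 0.05) or with fry (lowest adjusted p = 0.328). All 10 splits of these 6 libraries gave at least as many list calls, up to 63, so their number does not set the groups apart. The other lists had no call, with class medians from -0.50 for complement to 0.47 for efferocytosis.

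Genes changed in disease were last followed into recovery. Of the 64 genes called between disease and control in type 2 dendritic cells, 10 were called in the opposite direction between recovery and disease and 2 in the same direction between recovery and control. All 64 had the opposite sign in the second contrast, but both contrasts share the disease libraries, and in 20 simulations of unchanged groups 97.7% of the top genes did so. Those simulations called a mean of 0.55 genes between disease and control, with a mean of 0.05 called both ways and at most 1, and independent lists of this size would share 0.0910. Part of the excess may come from the shared disease libraries, too few to split. Median log2 changes of the 64 were 1.99 in disease, 1.35 back in recovery and 0.60 in recovery against control. The remainder and the sign, kept by 60, could come from the shared control libraries alone, which was not simulated. In monocyte-like cells 0 of 5 genes were called back (edgeR called 0 of 11669 there, DESeq2 91). All 5 had the opposite sign (97% in the simulations, which called a mean of 0.3 genes), and their median log2 values were 1.62, 1.01 and 0.15.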

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

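Tests of genes in the macrophage-like class (cluster 20) with at least 10 cells per library, the tests without each disease library, the clustering without called genes and the test of markers against all genes that rose were chosen only after the data were seen. The comparisons above use no genes of this class, since too few libraries had 20 such cells. With at least 10 cells there were 2 control, 3 disease and 3 recovery libraries, and 5 genes stood out as signals above control. Saa3, an acute-phase serum amyloid, stood at 0 CPM in both control libraries, 1681 ± 1005 in disease and 0.664 ± 1.15 in recovery (edgeR adjusted p = 0.00146 between disease and control). Pdpn, the membrane glycoprotein podoplanin, stood at 1.44 ± 2.04, 519.3 ± 97.2 and 15.6 ± 9.51 CPM (adjusted p = 4.23e-05). Inhba, the subunit of activin A, stood at 2.88 ± 4.07, 536 ± 146 and 33.2 ± 20.5 CPM (adjusted p = 0.000510). Slc41a2, a magnesium transporter, stood at 0, 29.17 ± 2.56 and 6.46 ± 1.95 CPM (adjusted p = 0.0115), and Ahnak2 at 0, 28.09 ± 7.17 and 9.63 ± 8.18 CPM (adjusted p = 0.0344).

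In the same test 202 of 6642 genes rose in disease and 149 fell. Met, the receptor of hepatocyte growth factor, rose from 5.31 ± 0.644 to 273 ± 70.8 CPM (adjusted p = 4.23e-05). The lectin Clec10a fell from 152 to 10.7 CPM (log2 -3.58 ± 0.53, adjusted p = 0.00308), Ciita, the activator of MHC class II genes, from 121 to 16.9 CPM (log2 -3.23 ± 0.50, adjusted p = 0.00279), and Axl, a receptor for dying cells, from 312 to 44.1 CPM (log2 -2.97 ± 0.34, adjusted p = 0.000436). Between disease and recovery 220 genes rose and 249 fell. Pdpn (log2 -4.87 ± 0.35) and Met (log2 -4.54 ± 0.30) fell, while the chemokine Ccl12 (1.37 to 71.0 CPM) and Ccnd1, cyclin D1 (9.51 to 83.0 CPM, log2 3.21 ± 0.38), rose. Between recovery and control 1 gene was called. Pdpn is among the genes that lead cluster 20, so its level and the naming of the cells are not independent. In this class the 12 macrophage markers summed to 12697 CPM in control, 5364 in disease and 10586 in recovery. There the 12 neutrophil markers summed to 8599, 30785 and 61560 CPM and the 10 T cell markers to 124, 21.3 and 267 CPM. Clustering without 636 called genes kept 293 of 398 cells and left 1 control, 3 disease and 2 recovery libraries, with 58 genes called between disease and control, 48 of them among the 351 above. That fit assumes the lone control library to vary like the other groups.

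The first pattern weighed is the higher level of these genes in macrophage-like cells of diseased mucosa, which cells of connective tissue or epithelium could bring as doublets or free RNA, although the CD45+ sort should remove them. In control, disease and recovery the 9 fibroblast markers summed to 120.5 ± 50.9, 239.2 ± 60.6 and 125 ± 110 CPM and the 11 epithelial markers to 6.01 ± 4.52, 14.65 ± 8.20 and 17.7 ± 4.74 CPM, against 514 ± 94.9 CPM of Pdpn in disease. Between control and disease a fibroblast marker gained a mean of 13.19 CPM and an epithelial marker 0.7857 CPM. The 202 genes that rose gained a median of 143.9 CPM (SD of the difference 19.9 and 18.8). So such cells, which would bring these markers too, did not carry the set as a whole. Without disease library 3, which gave most of the cells, the median log2 change of the called genes was 1.59 against 1.69, although the count of calls went from 351 to 140. RNA of neutrophils (sums above) was not tested and stays open, as do a state of resident cells and arriving cells. No biological explanation was tested.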

How the results depend on the processing

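Chosen only after the data were seen were named cells only, highest doublet scores removed, at least 10 cells, clusters by number, lists without free-RNA members, macrophage-like cells without each disease library and clustering without macrophage genes. Of 5724 values of named genes under alternatives, 5230 kept direction and side of the threshold, 238 lost the threshold, 255 passed it and 1 reversed. For class shares, of 153 these were 126, 14, 12 and 1, and for gene lists, of 2966, 2360, 600, 0 and 6. Where a value below differs, the cause was not tested, except that at least 50 cells, a left-out library or 2 groups leave fewer samples in the fit.

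Class shares between disease and control (1 call, macrophage-like cells) fell to 0 calls with 500 genes per cell or at resolutions 0.5 and 2.0. The same held with the replicate block, 2 groups in the fit, TMM factors, named cells only or the highest doublet scores removed. Leaving out a library gave 0 to 1. Between recovery and disease (0 calls) there were 2 with 500 genes per cell, 1 with TMM factors and 5 with named cells only, and 0 to 4 (without recovery library 1). The exact test over 3 groups (0 calls) gave 0 to 2 (without control library 3 or disease library 1).

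Over all cells, calls between disease and control (0) were 39 with the replicate block, 359 with DESeq2 and 86 with no filter on low counts, and 0 to 278 (without disease library 2). Between recovery and disease (154) they were 273 with the block, 16 with only 2 groups in the fit, 983 with DESeq2 and 389 with no filter, and 0 (without recovery library 2) to 666 (without disease library 2). Between recovery and control (0) they were 1 with the block, 23 with DESeq2 and 3 with no filter.

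Within classes, calls between disease and control (69) were 125 with the replicate block, 114 with 2 groups in the fit, 265 with DESeq2, 963 with no filter, 5 with at least 50 cells, 363 with at least 10 cells (351 of them in the macrophage-like class, not tested before), 134 with clusters by number and 30 adjusted over all classes together, and 35 (without disease library 3) to 216 (without disease library 2). Between recovery and disease (26) they were 101 at resolution 0.5, 373 with the block, 63 with 2 groups, 260 with DESeq2, 1365 with no filter, 13 with at least 50 cells, 40 with the highest doublet scores removed, 493 with at least 10 cells (469 in that class), 47 with clusters by number and 9 adjusted over all classes, and 7 (without recovery library 2) to 280 (without disease library 2). Between recovery and control (7) they were 4 at resolution 2.0, 871 with the block, 509 with DESeq2, 1087 with no filter, 3 with at least 50 cells, 4 with at least 10 cells, 3 adjusted over all classes and 4 with free-RNA genes left out, and 6 (without control library 1) to 1024 (without recovery library 1).

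Gene lists (57, 45 and 37 calls in the order above) had 0 with an estimated correlation or with fry. They had 40, 37 and 31 with free-RNA members left out, and 86, 91 and 57 with at least 10 cells, which adds classes. With clusters by number they had 79 between recovery and disease and 69 between recovery and control. The last comparison had 23 at 5% mitochondrial UMIs and 24 with at least 50 cells. Disease genes called back in recovery (10 of 69) were 63 of 69 at an unadjusted p and 95 of 265 with DESeq2.

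Reversed results were Ccr9 in monocyte-like cells between disease and control (log2 2.47, but -0.23 at resolution 0.5) and the erythroid share between recovery and disease (log2 1.23, but -0.13 at resolution 2.0). At resolution 0.5 the list Cell cycle in B cell precursor-like, recovery vs control, reversed (adjusted p = 0.546; over all alternatives 0.00280 to 0.926), as did the list Neutrophil granules in Neutrophil precursor-like, recovery vs control (0.735; 0.00494 to 0.940). Without disease library 1 the list Interferon gamma response in Monocyte-like, disease vs control, reversed (0.851; 4.03e-05 without disease library 2 to 0.869 with fry). So did the list Pattern recognition receptors in T cell-like, disease vs control (0.901; from 0.00414, and 0.0116 without control library 3), and the list Pattern recognition receptors in T cell-like, recovery vs disease (0.826; 0.00210 to 0.865, and 0.00864 without control library 2). Without recovery library 3 the list Oxidative phosphorylation in Neutrophil precursor-like, recovery vs disease, reversed (0.656; 2.79e-07 without recovery library 1 to 0.938).

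The replicate block is not the design, since no label says that a number is shared: correlations between libraries of the same number ran from -0.154 to 0.124 and 2 of 9 libraries correlated best with their own number. Depth may limit precision, but was not separated from the number of libraries. Between disease and control 12.5% of simulated 2-fold changes were recovered in type 2 dendritic cells (2 disease libraries) and 74% in monocyte-like cells (3).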

Other observations

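Of the tests in this part, the splits of the macrophage-like class and the setting of lymphocytes against neutrophils for free RNA were chosen only after the result was seen. Several kinds of leukocyte formed no class of their own, and their fixed markers, summed over all cells of a library, are given as values with no test (SD, n = 3). CD8 T cell markers stood at 206 ± 43.9 CPM in control, 163 ± 25.7 in disease and 303 ± 101 in recovery, and CD4 T cell markers at 35.5 ± 6.11, 24.3 ± 5.60 and 48.3 ± 11.0 CPM. Gamma delta T cell markers stood at 28.8 ± 10.7, 14.4 ± 6.50 and 26.3 ± 5.54 CPM. Regulatory T cell markers stood at 55.8 ± 1.23, 51.9 ± 15.3 and 56.6 ± 7.25 CPM. Langerhans cell markers stood at 37.5 ± 10.04, 24.5 ± 0.722 and 37.5 ± 13.8 CPM. Type 1 conventional dendritic cell markers stood at 702 ± 29.2, 639.8 ± 22.7 and 640.6 ± 36.5 CPM. Mast cell markers stood at 693 ± 44.0, 758 ± 76.2 and 576 ± 91.5 CPM. The type 2 innate lymphoid cell list, which holds the macrophage gene Arg1, stood at 42.4 ± 3.00, 119 ± 110 and 49.6 ± 3.82 CPM, with 245 CPM in disease library 3, the library with the most macrophage-like cells.

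Among markers of cells that a CD45 sort should remove, fibroblast markers stood at 7.55 ± 5.71, 15.5 ± 8.08 and 6.80 ± 0.870 CPM, epithelial markers at 16.1 ± 1.40, 14.99 ± 3.62 and 18.9 ± 1.79 CPM, and endothelial markers at 48.8 ± 2.65, 40.6 ± 6.30 and 43.8 ± 9.69 CPM. Mural cell markers stood at 13.9, 17.7 and 12.9 CPM and Schwann cell markers at 45.2, 52.3 and 39.4. Osteoblast and chondrocyte markers stood at 5.96, 9.43 and 4.65 CPM and muscle markers at 3.90, 3.63 and 5.17. Platelet and megakaryocyte markers stood at 113 ± 67.2, 110.3 ± 88.4 and 138 ± 51.5 CPM.

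The second pattern weighed is the inflammatory and NF-kB list, higher in disease than in control with the preset correlation alone. In neutrophil-like cells the list median of 0.825 became a mean of 0.2894 over clusters tested apart (0.824 in cluster 4, 0.646 in 17, -0.169 in 6 and -0.143 in 7), so a changed makeup of the class may carry part of it, while clusters 4 and 17 had positive medians. Free RNA of neutrophils could bring these genes to lymphocytes, where neutrophil markers had a median log2 change of -0.3161 in B cell-like cells against 0.271 for the list (SE of the difference 0.165), -0.03119 against 0.824 in T cell-like cells (SE 0.319) and 0.0317 against 0.0609 in B cell precursor-like cells (SE 0.147). The bound first set on these gaps was wrong, since in the neutrophils themselves the list stood 0.822 above the markers (SE 0.141), so free RNA stays open in all 3 classes. A response of the cells to disease stays open too, and no biological explanation was tested.

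The third pattern weighed is the ribosomal protein list, higher in recovery than in disease in all 8 classes tested with the preset correlation alone. A difference in UMIs per cell could give this, but with cells in the middle of each class's UMI range the mean of the class medians was 0.4742 ± 0.0859 against 0.511 ± 0.134 (SD over classes). DESeq2 size factors gave 0.513, so the choice between these and TMM did not carry it. A difference in handling between groups and growth of cells in recovery were not tested.

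For 3 libraries against 3 there are 10 splits, too few for a share under 0.05, so the real value and the highest other are given in the order disease against control, recovery against disease, recovery against control. Class shares had 1, 0 and 0 calls, other splits at most 0, 1 and 7, and 1, 10 and 10 splits gave as many, the real one included. Genes over all cells had 0, 154 and 0 calls, others at most 0, 0 and 0, and 10, 1 and 10 splits gave as many. Genes within classes had 69, 26 and 7 calls, others at most 12, 3 and 92, and 1, 1 and 2 splits gave as many. Gene lists had 57, 45 and 37 calls, others at most 74, 50 and 63, and 3, 4 and 10 splits gave as many. In macrophage-like cells between recovery and disease the real split had 469 calls, the others at most 0, and 1 split gave as many. The split with 92 genes and 7 shares sets control libraries 1 and 2 with recovery library 1, whose unnamed cells made up 44.9%, 42.2% and 23.8%, against control library 3 and recovery libraries 2 and 3 (5.35%, 8.99% and 6.47%), and so points to a structure of the samples other than the groups.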
